A study of Mus musculus with 90 samples.

How the data were processed

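The series holds 90 mouse samples, and the 27 RNA libraries of day 7 of differentiation were analysed. Per the labels' protocols, confluent LGT cells were induced for 48 hours with 20 nM insulin, 1 nM T3, 1 µM dexamethasone, 500 µM IBMX, 125 µM indomethacin and 1 µM rosiglitazone, and then kept for 5 days in insulin and T3. The 14 ATAC, 14 H3K27ac and 35 CUT&Tag samples are not analysed here. Groups and replicate numbers came from the sample titles, and all 27 columns of the tables matched a title.

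The authors deposited 1 table of estimated (expected) counts per gene symbol for batch 12 and 1 for batch 13, each with 35396 genes. The submitters' processing notes name Salmon, a quantifier that assigns reads to transcripts, and the mouse build mm39. The Salmon settings, its version and the transcript annotation are not given in the sources used here. Such a tool shares reads between transcripts that are alike, so counts of close copies and overlapping genes (Pagr1a, Zxda, Zbed6, Rps12l1) are uncertain. The name tables at hand follow another build, GRCm38.p6, so no coordinates are given, and symbols are those of the deposited tables.

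The deposited estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Each batch was fitted with all its libraries in 1 model, after filterByExpr (13397 genes kept in batch 12 and 13786 in batch 13) and TMM scaling, with the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change is its size divided by the square root of F, an approximation. For large folds with few counts in a group it can lie below the counting error, as for Adipoq with 27 counts in KO-MED1. The comparisons were KO-EBF2 and KO-CTD against KO-EV and KO-CTD against KO-EBF2 in batch 12, and every group against KO-EV and against KO-EBF2 in batch 13. The effects of KO-EBF2 in the batches were tested against each other through a model of both with their difference as its term. Levels can differ by batch, and were set side by side across batches without a test, in a figure and to weigh technical explanations. A test of KO-EV between the batches served only to pick the genes of a batch axis. In batch 12 the replicate numbers may pair KO-EBF2 with KO-EV. The 3 same-numbered pairs of libraries correlated at 0.164, 0.109 and 0.204 in their deviations from the group means. This possible pairing comes from the data, as the labels name no shared day or culture. No other comparison had all its pairs over 0.1. Where a group had 0 counts, the fold is a lower bound against 3 counts in each of its libraries. With 1 to 3 counts, the ratio of CPM is given with an exact 95% counting interval. Intervals and bounds cover counting error only.

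Gene lists were tested with camera of limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2, for lists with at least 5 tested members, and adjusted over the 22 lists. The 23 lists were brown thermogenic, general and white adipocyte, lipid synthesis, cholesterol synthesis, fatty acid oxidation, citric acid cycle, nuclear oxidative phosphorylation, mitochondrially encoded, futile cycle, progenitor, extracellular matrix, smooth muscle, skeletal muscle, bone and cartilage, endothelial, macrophage, interferon response, inflammatory, endoplasmic reticulum stress, p53 target, proliferation and chromatin partner genes. All 12 macrophage markers were in the tables, but fewer than 5 passed the filter in either batch, so that list was not tested. Of the 26 interferon symbols 25 were in the tables. For the transfer of a profile, genes of 1 batch past the threshold with a log2 fold change of at least 1 were tested with camera in the other batch.

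The lists, tests, comparisons and rule for named genes were fixed before the data were examined. Ebf2, Ucp1, Pparg, Adipoq, Fus and Med1 were named throughout. KO-EBF2 against KO-EV in each batch and both KO-CTD comparisons named 8 genes per direction, and the others 4, with the largest fold change among genes past the threshold, at a mean of at least 5 CPM over the batch and with no overlap between the 3 values of each group, which chance gives in 10% of cases. Predicted genes and pseudogenes were passed over. Each list gave up to 4 members with the smallest adjusted p and at least 1 CPM.

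Depth was 18333281 to 35399946 counts per library. On simulated data drawn from the real means with 200 changed genes, edgeR recovered 34% of genes changed 1.25-fold, 74% of 1.5-fold, 78% of 2-fold and 96% of 4-fold changes in batch 12 (8 false calls among 13069 genes), and 42%, 82%, 90% and 92% in batch 13 (14 false calls among 13007). For the difference between batches it recovered 12.2%, 62%, 77.6% and 93.9% (13 false calls among 13046). The real comparisons called 15.6% to 79.3% of tested genes, far more than were changed here, so these false calls need not hold for them. Camera called the simulated raised list and 0 of 20 unchanged lists in both batches. The simulated genes varied independently, while the members of the real lists had a median estimated correlation of 0.151. The simulation therefore cannot show how often camera calls an unchanged list of correlated genes.

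The alternatives were DESeq2 1.42.0, DESeq2 size factors in place of TMM, no filter on low counts, the replicate number as a block, fits of only the compared groups, each replicate left out, and for lists an estimated correlation, fry and genes of at least 5 CPM. Added after the data were seen were size factors for the lists, batch 13 results without KO-IDR replicate 4, and an estimated correlation for the transfer. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.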

Results

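Total RNA was sequenced from LGT cells, an immortalized mouse brown preadipocyte line, after 7 days of differentiation. The 27 RNA libraries fell into 9 groups of 3, named here as their titles name them. Batch 12 held KO-CTD, KO-EBF2 and KO-EV (replicates 1 to 3), and batch 13 held KO-EBF2, KO-EV, KO-FUS, KO-IDR, KO-MED1 and KO-P>A (replicates 4 to 6). The titles do not say what the parts of these names stand for, and the genotype label was the same in all libraries, so groups are named and not interpreted. Libraries held 18333281 to 35399946 estimated gene counts. The other 63 samples of the series, which were ATAC, H3K27ac and CUT&Tag libraries, are not analysed here. Levels are in CPM, counts scaled to library size, as mean ± SD over 3 libraries, and log2 fold changes are given ± an approximate SE. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Replicates of each group differed by more than sampling noise. KO-IDR replicate 4 stood apart from replicates 5 and 6 of its group. It had a chi-square per degree of freedom of 24.57 and 25.96 against them and 6.14 between those other libraries. It also had 1.86% mitochondrially encoded counts against 2.90% and 2.75%.

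Ebf2, the early B-cell factor that marks brown and beige fat precursors, was lowest in the KO-EV group of each batch. It stood at 1.82 ± 0.258 CPM in KO-EV, 26.8 ± 4.97 in KO-EBF2 and 34.8 ± 3.67 in KO-CTD in batch 12. In batch 13 it stood at 3.68 ± 0.773 CPM in KO-EV, 16.0 ± 2.01 in KO-FUS, 26.0 ± 0.258 in KO-EBF2, 32.1 ± 4.22 in KO-MED1, 71.2 ± 13.8 in KO-IDR and 101 ± 1.32 in KO-P>A. Against KO-EV of its batch, Ebf2 rose by 3.98 ± 0.16 on the log2 scale in KO-EBF2 and 4.28 ± 0.16 in KO-CTD of batch 12 (edgeR adjusted p at most 8.21e-11). The rises in batch 13 were 2.76 ± 0.16 in KO-EBF2, 2.22 ± 0.16 in KO-FUS, 4.27 ± 0.15 in KO-IDR, 3.15 ± 0.16 in KO-MED1 and 4.77 ± 0.15 in KO-P>A (edgeR adjusted p at most 6.1e-11). The groups also differed from KO-EBF2 of their own batch, with log2 fold changes of -0.54 ± 0.13 in KO-FUS, 1.51 ± 0.12 in KO-IDR and 2.01 ± 0.12 in KO-P>A (edgeR adjusted p at most 0.000619). Smaller differences, 0.39 ± 0.12 in KO-MED1 (edgeR adjusted p = 0.00585) and 0.30 ± 0.11 in KO-CTD (edgeR adjusted p = 0.0346), were less certain. The KO-MED1 call was lost without KO-MED1 replicate 4 (0.28; edgeR adjusted p = 0.0551). The KO-CTD call was lost without KO-CTD replicate 3 (0.23; edgeR adjusted p = 0.164) or KO-EBF2 replicate 2 (0.19; 0.152). It was also lost without KO-CTD replicate 2 (edgeR adjusted p = 0.0707) or KO-EBF2 replicate 3 (0.0651), where the fold change stayed at 0.31 and fewer libraries were tested.

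Fus, which encodes an RNA-binding protein, was at 240 ± 7.01 CPM in KO-EBF2 and 305 ± 21.4 in KO-EV of batch 12, a log2 fold change of -0.23 ± 0.06 (edgeR adjusted p = 0.00356). In batch 13 it was at 184 ± 1.61 CPM in KO-EBF2 and 135 ± 9.63 in KO-EV, a change of 0.39 ± 0.06 (edgeR adjusted p = 8.23e-06). Fus rose over KO-EV by 1.06 ± 0.06 in KO-FUS, 0.85 ± 0.06 in KO-IDR and 0.93 ± 0.06 in KO-MED1 (edgeR adjusted p at most 5.67e-11). It did not pass the test against KO-EV in KO-P>A, at -0.07 ± 0.06 (edgeR adjusted p = 0.397), or in KO-CTD, at 0.05 ± 0.06 (edgeR adjusted p = 0.612). Against KO-EBF2, Fus was higher by 0.67 ± 0.06 in KO-FUS, 0.47 ± 0.06 in KO-IDR, 0.54 ± 0.06 in KO-MED1 and 0.28 ± 0.06 in KO-CTD. It was lower in KO-P>A at -0.46 ± 0.06 (edgeR adjusted p at most 0.00102). Med1, a subunit of the Mediator coactivator, stood at 82.0 ± 5.0 CPM in KO-MED1 and 56.6 ± 5.01 in KO-EV of batch 13, a rise of 0.56 ± 0.11 (edgeR adjusted p = 6.83e-05), and was 0.62 ± 0.11 above KO-EBF2 (edgeR adjusted p = 2.25e-05). It was lower in KO-FUS than in KO-EV, at -0.46 ± 0.11 (edgeR adjusted p = 0.000655), and than in KO-EBF2, at -0.40 ± 0.11 (edgeR adjusted p = 0.00217). In batch 12 Med1 was called lower in KO-EBF2 than in KO-EV, at -0.19 ± 0.08 (edgeR adjusted p = 0.0384). The call was lost with DESeq2, in a fit of only these 2 groups and when any of 5 of the 6 libraries was left out. The fold ran from -0.17 to -0.22 in these fits, apart from -0.1 without KO-EV replicate 1. The other comparisons gave -0.09 to 0.13 for Med1 and did not pass the test (edgeR adjusted p at least 0.164). Its means in the other groups were 45.7 CPM in KO-CTD, 39.9 in KO-EBF2 and 49.3 in KO-EV of batch 12, and 56.8 in KO-EBF2, 38.3 in KO-FUS, 53 in KO-IDR and 54.4 in KO-P>A of batch 13.

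**Figure D1:**
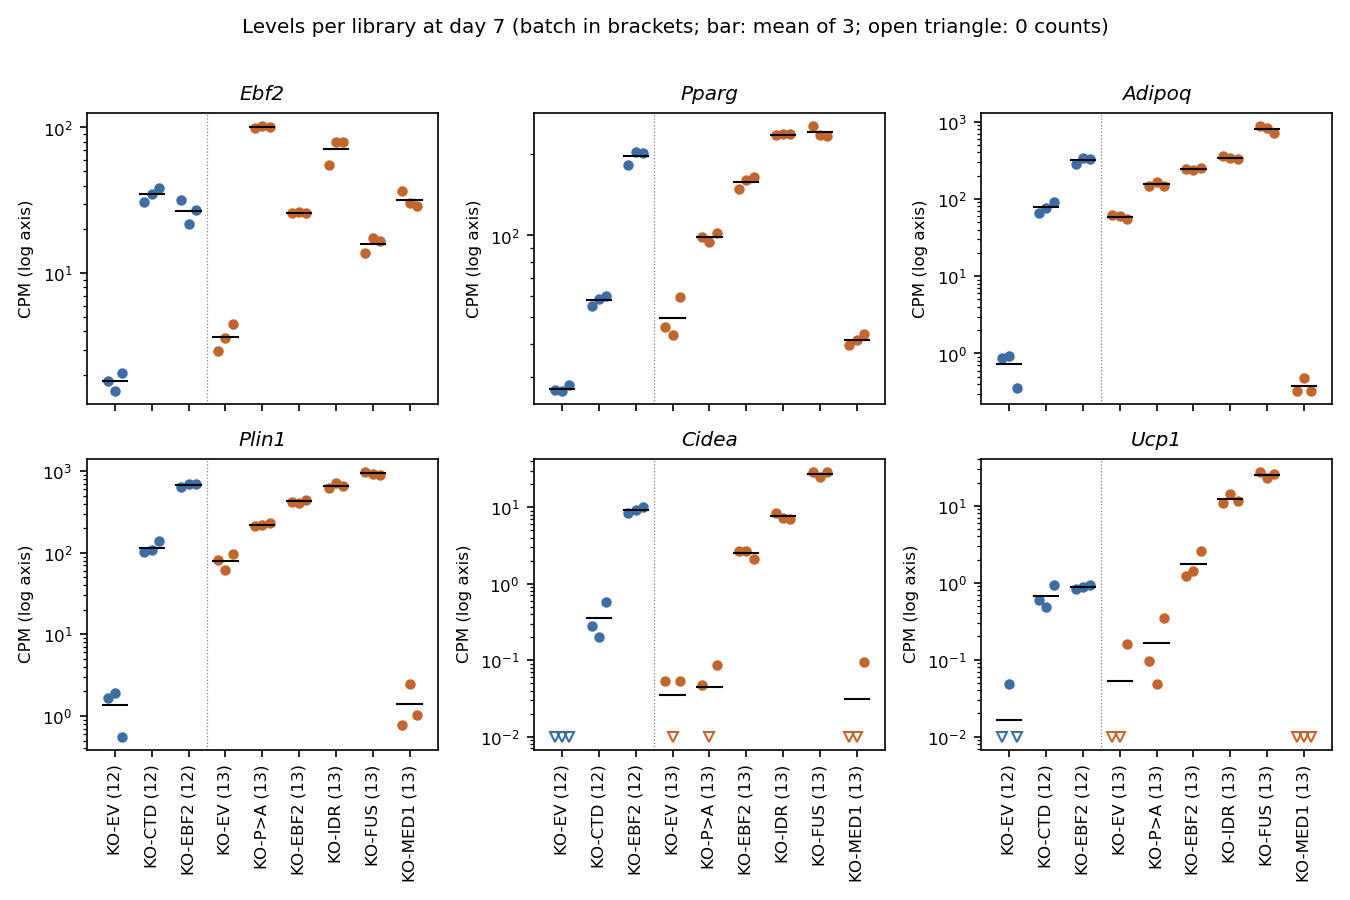
Level of Ebf2, Pparg, Adipoq, Plin1, Cidea and Ucp1 in each of the 27 libraries, in CPM on a log axis, by group. Points are libraries, bars are means of 3, open triangles at the foot of the axis are libraries with 0 counts, blue is batch 12 and orange is batch 13; Adipoq averaged 318 in KO-EBF2 and 0.721 in KO-EV of batch 12, and 804 in KO-FUS and 0.377 in KO-MED1 of batch 13.

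The first comparison asked how day 7 transcriptomes of KO-EBF2 differed from those of KO-EV in batch 12. Genes of the fat cell were far higher in KO-EBF2. Pparg, the nuclear receptor that drives fat cell differentiation, averaged 195 ± 12.3 CPM against 27.3 ± 0.734. Adipoq, which encodes the hormone adiponectin, averaged 318 ± 30 against 0.721 ± 0.314. These were log2 fold changes of 2.95 ± 0.07 and 8.92 ± 0.19 (edgeR adjusted p at most 1.08e-13). Ucp1, the uncoupling protein of brown fat, was low in both groups, at 0.872 ± 0.0541 CPM in KO-EBF2 and 1 count over the 3 KO-EV libraries, a ratio of 59.8 (95% counting interval 10.4 to 2400; edgeR adjusted p = 7.41e-06). In all, 8555 of 13397 tested genes changed, 4258 higher and 4297 lower.

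Among the genes with the largest rises were the lipid droplet genes Cidec (9.51 ± 0.20) and Plin1 (9.08 ± 0.21; 675 ± 35 CPM against 1.38 ± 0.718), Cfd, which encodes adipsin (9.37 ± 0.26), and Thrsp, a regulator of lipogenesis (9.68 ± 0.29). Mb, which encodes the oxygen-binding protein myoglobin, rose by 11.12 ± 0.29 on the log2 scale, from 0.0840 to 189 ± 14.2 CPM (edgeR adjusted p = 1.8e-13, and at most 8.26e-13 for the others). The aldehyde dehydrogenase gene Aldh3b2 had 1 count in KO-EV and a ratio of 946 (169 to 37400). Slc25a34, of the mitochondrial carrier family, had 3 counts and a ratio of 597 (204 to 2900). Among the genes with the largest falls were Esm1, or endocan (-4.65 ± 0.15; 3.43 CPM against 97.4), the matrix protease gene Mmp3 (-3.70 ± 0.25), Grem1, which encodes an antagonist of bone morphogenetic proteins (-3.68 ± 0.12), the proteoglycan gene Dcn (-3.55 ± 0.11; 9.36 CPM against 120) and the acute-phase gene Saa3 (-3.43 ± 0.18). Tspan11 (-4.39 ± 0.23), Galnt17 (-3.68 ± 0.15) and Crabp1, which binds retinoic acid (-3.49 ± 0.17), fell as well (edgeR adjusted p at most 5.51e-09).

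Of 29 tested general adipocyte genes, 29 rose (29 adjusted over the list alone), by a median of 4.63, among them the fatty acid carrier gene Fabp4 (4.63 ± 0.09; 1921 CPM against 83.9) and the lipase gene Lpl (3.94 ± 0.08). Camera gave adjusted p = 5.52e-19 for this list and adjusted p = 0.131 with an estimated correlation. In the brown thermogenic list, 10 of 16 members were higher and 1 lower (11 adjusted over the list alone; camera adjusted p = 0.00664, and adjusted p = 0.229 with an estimated correlation). Its median was 1.10, also with Cidea at its bound. Cox7a1 (3.51 ± 0.10), the potassium channel gene Kcnk3 (6.00 ± 0.30) and Prdm16, a transcriptional regulator of brown fat (4.85 ± 0.32), rose, and Cidea was higher by at least 6.13 on the log2 scale, at 9.14 CPM against 0 counts. Lipid synthesis genes were higher in 17 of 18 cases, with 1 lower (18 adjusted over the list alone; camera adjusted p = 3.61e-07, and adjusted p = 0.226 with an estimated correlation), including Scd1 (4.65 ± 0.14) and Dgat1 (2.75 ± 0.07).

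Genes of mitochondrial metabolism rose together in KO-EBF2, in which 3.38% ± 0.12 of counts were mitochondrially encoded, against 2.00% ± 0.26 in KO-EV. Of the nuclear genes of oxidative phosphorylation, 70 of 71 rose (70 adjusted over the list alone), with a median of 1.04 (camera adjusted p = 4.94e-21, and adjusted p = 0.298 with an estimated correlation), for example Cycs, or cytochrome c (1.56 ± 0.07), and Atp5b (1.34 ± 0.06). Fatty acid oxidation genes rose in 21 of 22 cases (21 adjusted over the list alone; camera adjusted p = 2.26e-12, and adjusted p = 0.131 with an estimated correlation), among them Acadm (1.91 ± 0.06). All 20 citric acid cycle genes rose (20 adjusted over the list alone; camera adjusted p = 5.12e-11, and adjusted p = 0.131 with an estimated correlation), Cs, or citrate synthase, by 1.76 ± 0.06. All 13 mitochondrially encoded genes rose (13 adjusted over the list alone; camera adjusted p = 0.000818, and adjusted p = 0.434 with an estimated correlation), mt-Co2 by 1.15 ± 0.09.

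Skeletal muscle genes were higher in 17 of 19 cases and lower in 1 (18 adjusted over the list alone), with a median of 4.19, or 2.96 with genes at 0 counts set to their bounds (camera adjusted p = 4.37e-07, and adjusted p = 0.131 with an estimated correlation). Acta1, the actin of skeletal muscle (4.48 ± 0.22; 15.2 CPM against 0.736), and the intermediate filament gene Des (2.09 ± 0.17) were among them. Inflammatory genes were lower in 9 of 13 cases and higher in 2 (11 adjusted over the list alone; camera adjusted p = 0.00664, and adjusted p = 0.298 with an estimated correlation), the adhesion gene Vcam1 by a log2 fold change of -1.70 ± 0.08. Extracellular matrix genes went both ways, 20 of 30 lower and 7 higher (27 adjusted over the list alone; camera adjusted p = 0.0432, and adjusted p = 0.649 with an estimated correlation): Dcn fell while the collagen gene Col6a2 rose by 2.03 ± 0.08. Endothelial markers were lower in 5 of 6 cases and higher in 1 (6 adjusted over the list alone; camera adjusted p = 0.0489, and adjusted p = 0.226 with an estimated correlation). Kdr had a log2 fold change of -1.79 ± 0.31 from 2.55 CPM. The other 11 lists were not called, and their counts higher and lower were 2 and 9 of 25 for the interferon response (camera adjusted p = 0.176), 4 and 3 of 7 for futile cycles (0.466), 2 and 9 of 18 for progenitor genes (0.0620), 5 and 6 of 14 for p53 targets (0.773) and 2 and 3 of 6 for bone and cartilage markers (0.512). They were 5 and 3 of 8 for white adipocyte genes (camera adjusted p = 0.157), 19 and 6 of 32 for proliferation (0.118), 11 and 5 of 20 for the stress response of the endoplasmic reticulum (0.413), 9 and 6 of 21 for cholesterol synthesis (0.512), 3 and 5 of 11 for smooth muscle (0.260) and 4 and 15 of 30 for chromatin partners (0.0641).

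The second comparison set KO-CTD against KO-EV in batch 12. Fat cell genes were higher in KO-CTD too. Adipoq averaged 77.5 ± 12.2 CPM (6.81 ± 0.20), Plin1 116 ± 19.7 CPM (6.47 ± 0.21) and Pparg 57.8 ± 2.36 CPM (1.13 ± 0.07; edgeR adjusted p at most 4.18e-08 for the 3 genes). Mb (8.45 ± 0.34), Thrsp (7.30 ± 0.37), Cfd (6.98 ± 0.29), Cidec (6.79 ± 0.21) and the amino acid transporter gene Slc36a2 (6.22 ± 0.24) also rose (edgeR adjusted p at most 1.66e-09). Aldh3b2 had a ratio of 157 (27.7 to 6230) over the 1 count of KO-EV. Ucp1 was at 0.672 ± 0.234 CPM, a ratio of 47.1 (8.07 to 1900; edgeR adjusted p = 0.000249). Mmp3 (-2.80 ± 0.22), Grem1 (-2.43 ± 0.10), Saa3 (-1.55 ± 0.15), Esm1 (-1.53 ± 0.12) and the integrin gene Itgb7 (-1.41 ± 0.10) fell (edgeR adjusted p at most 4e-06). So did Pgm5 (-1.70 ± 0.14), the matrix protein gene Spon2 (-1.68 ± 0.17) and Tspan11 (-1.60 ± 0.18; edgeR adjusted p at most 1.63e-05 for these 3). The number of changed genes was 2093 of 13397, 1202 higher and 891 lower. It rested in part on single libraries, with 1184 genes without KO-CTD replicate 3, 1277 without KO-EV replicate 2 and 1322 without KO-CTD replicate 1.

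General adipocyte genes rose in 28 of 29 cases in KO-CTD (28 adjusted over the list alone), with a median of 3.06 (camera adjusted p = 1.15e-38, and adjusted p = 0.0591 with an estimated correlation). Fatty acid oxidation genes rose in 20 of 22 cases (20 adjusted over the list alone; camera adjusted p = 1.64e-16, and adjusted p = 0.130 with an estimated correlation). Acadm had a log2 fold change of 0.72 ± 0.06. Of the oxidative phosphorylation genes, 32 of 71 rose (45 adjusted over the list alone) by small amounts, with a list median of 0.23 (camera adjusted p = 3.44e-12, and adjusted p = 0.522 with an estimated correlation). Ndufs2 had a log2 fold change of 0.42 ± 0.06. Mitochondrially encoded genes made up 2.48% ± 0.15 of counts in KO-CTD, and 6 of 13 rose (9 adjusted over the list alone; camera adjusted p = 0.00207, and adjusted p = 0.574 with an estimated correlation). Brown thermogenic genes were higher in 7 of 16 cases and lower in 2 (11 adjusted over the list alone; camera adjusted p = 0.00366, and adjusted p = 0.185 with an estimated correlation). Cox7a1 had a log2 fold change of 1.96 ± 0.10. White adipocyte genes were higher in 4 of 8 cases and lower in 1 (7 adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.189 with an estimated correlation), among them Retn, which encodes resistin (5.58 ± 0.22). p53 targets were lower in 3 of 14 cases and higher in 1 (6 adjusted over the list alone; camera adjusted p = 0.0109, and adjusted p = 0.153 with an estimated correlation, and camera adjusted p = 0.0542 among genes of at least 5 CPM). No interferon response gene passed the edgeR test as run here (0 of 25, 0 adjusted over the list alone; camera adjusted p = 0.521). Stat1, higher at 0.32 ± 0.11, was called by DESeq2. With no filter on low counts and in a fit of only these 2 groups, edgeR called Stat1 higher (0.32). In both fits it called Ifit2 (-0.31), Oasl1 (-0.42) and Mx2 (-0.49) lower. Single genes of this list therefore stay open, and these went both ways. In the skeletal muscle list 1 of 19 genes was higher (0 adjusted over the list alone; camera adjusted p = 0.718).

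KO-CTD was then compared with KO-EBF2. The fat cell genes that rose in both stood lower in KO-CTD: Pparg by a log2 fold change of -1.83 ± 0.07 and Adipoq by -2.10 ± 0.12 (edgeR adjusted p at most 1.61e-09). Ucp1 did not pass the test, at -0.43 ± 0.37 (edgeR adjusted p = 0.347). The largest falls were in Itih4, of the inter-alpha-trypsin inhibitor family (-6.57 ± 0.13; 1.02 CPM against 93.1), the cytochrome P450 gene Cyp2f2 (-5.24 ± 0.13), the protease gene Tmprss6 (-4.53 ± 0.18), the peroxisomal thiolase gene Acaa1b (-4.44 ± 0.24), Slc25a34 (-4.30 ± 0.18), the carbonyl reductase gene Cbr2 (-4.22 ± 0.11), Acta1 (-4.22 ± 0.21) and Gprc5c (-3.95 ± 0.16). Higher in KO-CTD were Galnt17 (3.20 ± 0.16), Esm1 (3.13 ± 0.15), Tspan11 (2.79 ± 0.26), Cd300lb (2.58 ± 0.16), Crabp1 (2.56 ± 0.18), Cpxm1 (2.49 ± 0.15), Serpina3g (2.45 ± 0.16) and Gfra2, a receptor of the GDNF family (2.43 ± 0.16). In all 7412 genes changed, 3602 higher and 3810 lower.

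Of the oxidative phosphorylation genes, 69 of 71 were lower in KO-CTD than in KO-EBF2 (69 adjusted over the list alone; camera adjusted p = 7.01e-22, and adjusted p = 0.283 with an estimated correlation), with a median of -0.82. General adipocyte genes were lower in 28 of 29 cases and higher in 1 (29 adjusted over the list alone; camera adjusted p = 7.32e-14, and adjusted p = 0.154 with an estimated correlation). Brown thermogenic genes were lower in 9 of 16 and higher in 1 (11 adjusted over the list alone; camera adjusted p = 0.00449, and adjusted p = 0.257 with an estimated correlation). Kcnk3 had a log2 fold change of -3.47 ± 0.23. Skeletal muscle genes were lower in 17 of 19 cases and higher in 1, with a median of -3.85, or -3.02 with bounds (18 adjusted over the list alone; camera adjusted p = 2.29e-08, and adjusted p = 0.0843 with an estimated correlation). Extracellular matrix genes were higher in 21 of 30 cases and lower in 4 (25 adjusted over the list alone; camera adjusted p = 6.39e-05, and adjusted p = 0.426 with an estimated correlation). Dcn had a log2 fold change of 2.21 ± 0.11. Inflammatory genes were higher in 8 of 13 cases and lower in 1 (9 adjusted over the list alone; camera adjusted p = 0.00140, and adjusted p = 0.257 with an estimated correlation). The chemokine gene Ccl2 had a log2 fold change of 1.37 ± 0.07. Progenitor genes were higher in 9 of 18 cases and lower in 3 (15 adjusted over the list alone; camera adjusted p = 0.0191, and adjusted p = 0.283 with an estimated correlation). Chromatin partners were higher in 13 of 30 and lower in 2 (14 adjusted over the list alone; camera adjusted p = 0.0191, and adjusted p = 0.426 with an estimated correlation).

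KO-EBF2 and KO-EV were compared again in batch 13, in which KO-EV itself held fat cell transcripts. Adipoq stood at 244 ± 8.24 CPM in KO-EBF2 and 59.1 ± 3.40 in KO-EV (1.98 ± 0.07). Pparg stood at 157 ± 7.61 and 49.5 ± 8.74 (1.61 ± 0.08; edgeR adjusted p at most 2.39e-13). Ucp1 was at 1.74 ± 0.748 CPM against 3 counts, a ratio of 34.1 (11.4 to 168; edgeR adjusted p = 2.09e-06). Cidea stood at 2.5 ± 0.331 CPM against 2 counts, a ratio of 75.8 (20.6 to 632). Car3, the carbonic anhydrase abundant in fat and muscle, reached 1041 ± 42.1 CPM against 5.14 ± 1.80 (7.62 ± 0.16; edgeR adjusted p = 1.27e-18). Tmem178 (7.75 ± 0.19), Syt13 of the synaptotagmin family (6.71 ± 0.32), the sorting receptor gene Sorcs1 (5.75 ± 0.16) and Cyp2f2 (5.29 ± 0.17) also rose (edgeR adjusted p at most 1.18e-13). Ppp2r2b, a regulatory subunit of protein phosphatase 2A, had a ratio of 248 (68.3 to 2050). Pagr1a was called higher as well (6.43 ± 1.44; edgeR adjusted p = 0.000559), but its transcripts overlap another gene and its counts are uncertain.

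Some falls in batch 13 took genes from clear expression to almost none. Peg10, an imprinted gene, had 0 counts in KO-EBF2 and 3.97 CPM in KO-EV, and was at least 26.7-fold lower. Its imprinted neighbour Sgce fell from 12.9 to 0.0734 CPM (-7.26 ± 0.31). Dnah1, an axonemal dynein, had 2 counts against 23.0 CPM (ratio 0.00143, 0.000173 to 0.00517), and the palmitoyltransferase gene Zdhhc15 1 count against 13.1 CPM (ratio 0.00125, 3.15e-05 to 0.00697). Unc93b1, needed for the trafficking of Toll-like receptors (-6.47 ± 0.22), the potassium channel subunit gene Kcne4 (-6.26 ± 0.26), Aplp1 (-6.14 ± 0.28) and the collagen gene Col11a1 (-6.07 ± 0.32) fell likewise (edgeR adjusted p at most 7.45e-13). The number of changed genes was 8754 of 13786, 4572 higher and 4182 lower.

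General adipocyte genes rose in 29 of 30 cases in batch 13 (29 adjusted over the list alone), with a median of 2.08 (camera adjusted p = 3.83e-13, and adjusted p = 0.0857 with an estimated correlation). Cidec had a log2 fold change of 3.02 ± 0.09. Fatty acid oxidation genes rose in 20 of 22 cases (21 adjusted over the list alone; camera adjusted p = 1.76e-10, and adjusted p = 0.0857 with an estimated correlation). Hadha had a log2 fold change of 1.08 ± 0.05. Oxidative phosphorylation genes were higher in 46 of 71 cases and lower in 1 (47 adjusted over the list alone; camera adjusted p = 2e-05, and adjusted p = 0.595 with an estimated correlation), with a median of 0.33, and mitochondrially encoded counts made up 1.77% ± 0.04 against 1.16% ± 0.04. Brown thermogenic genes were higher in 13 of 22 cases and lower in 4 (17 adjusted over the list alone; camera adjusted p = 0.0438, and adjusted p = 0.201 with an estimated correlation). Kcnk3 had a log2 fold change of 2.96 ± 0.10. The brown thermogenic call was lost among genes of at least 5 CPM (camera adjusted p = 0.0522). Interferon response genes rose in 24 of 25 cases (24 adjusted over the list alone; camera adjusted p = 3.97e-11, and adjusted p = 0.201 with an estimated correlation), with a median of 1.79, for example the transcription factor gene Stat1 (2.12 ± 0.07) and the GTPase gene Gbp2 (1.83 ± 0.08).

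The lists that moved down in batch 13 were those of matrix, contractile, stress, division and cholesterol synthesis genes. Extracellular matrix genes were lower in 22 of 30 cases and higher in 6 (28 adjusted over the list alone; camera adjusted p = 7.41e-05, and adjusted p = 0.190 with an estimated correlation). The protease gene Mmp2 had a log2 fold change of -2.10 ± 0.05. Smooth muscle genes were lower in 9 of 11 cases and higher in 1 (10 adjusted over the list alone; camera adjusted p = 0.000255, and adjusted p = 0.160 with an estimated correlation). Acta2 had a log2 fold change of -1.94 ± 0.09. The endoplasmic reticulum stress list was lower in 15 of 20 cases and higher in 2 (17 adjusted over the list alone; camera adjusted p = 2.22e-05, and adjusted p = 0.168 with an estimated correlation). Gdf15 stood at -2.87 ± 0.09 and Atf4 at -1.23 ± 0.06. Proliferation genes were lower in 22 of 32 cases and higher in 3 (26 adjusted over the list alone; camera adjusted p = 0.000236, and adjusted p = 0.168 with an estimated correlation). Cholesterol synthesis genes were lower in 14 of 21 and higher in 5 (19 adjusted over the list alone; camera adjusted p = 0.000499, and adjusted p = 0.168 with an estimated correlation). Ldlr had a log2 fold change of -1.51 ± 0.06. Skeletal muscle genes were higher in 2 of 9 cases (2 adjusted over the list alone; camera adjusted p = 0.777).

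**Figure D2:**
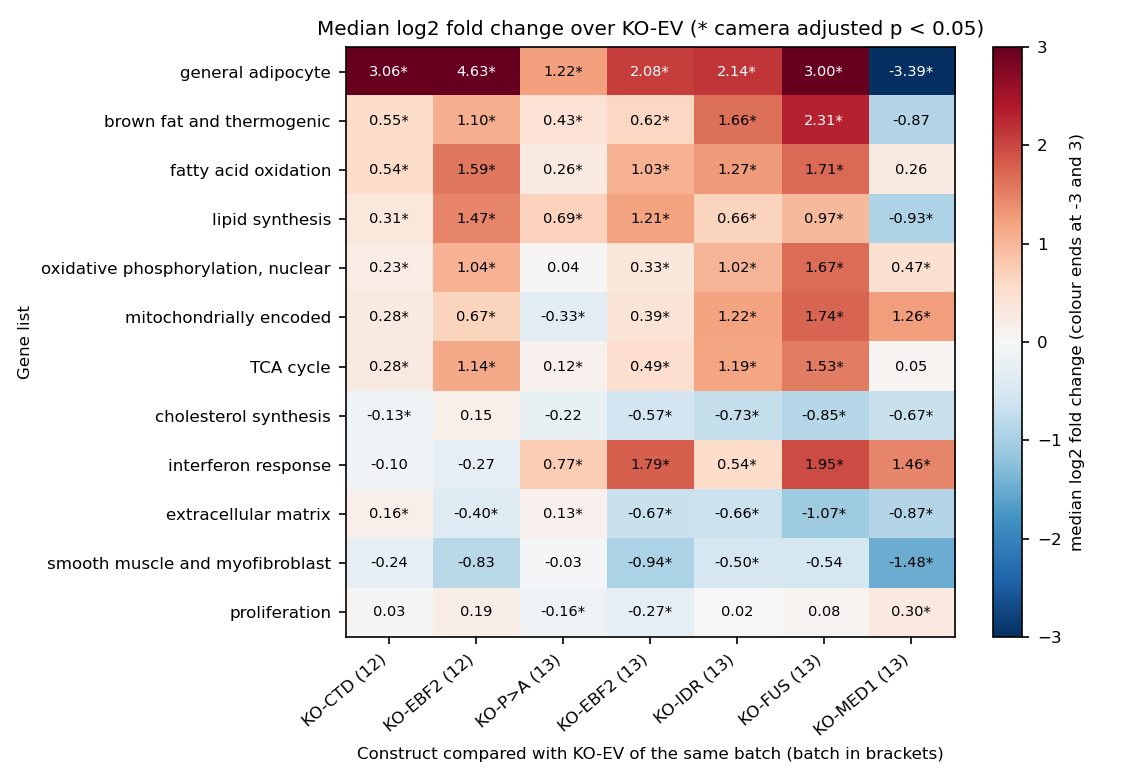
Median log2 fold change against KO-EV of the same batch for 12 gene lists (vertical) and 7 groups (horizontal), as colour and number, with genes at 0 counts set to their bounds. Stars mark lists with a camera adjusted p under 0.05; the general adipocyte list ranged from 4.63 in KO-EBF2 of batch 12 to -3.39 in KO-MED1.

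The effect of KO-EBF2 over KO-EV was tested for a difference between the batches, as an interaction in 1 model over both. It differed in 7756 of 14093 genes by edgeR's test, 3725 with a higher and 4031 with a lower log2 fold change in batch 13. Across 13170 genes tested in both batches the fold changes had Pearson r = 0.436 and Spearman rho = 0.391, and genes are not independent replicates. Of the genes called in either batch, 2155 rose in both, where independent lists would share 1405, and 2080 fell in both, where independent lists would share 1331. Another 760 genes rose in batch 12 and fell in batch 13, and 859 did the reverse. In list tests of this difference, chosen after the data were seen, interferon response genes had the higher effect in batch 13 in 22 of 25 cases (camera adjusted p = 4.78e-10, and adjusted p = 0.283 with an estimated correlation). General adipocyte genes had the lower effect there in 25 of 30 cases and the higher in 2 (camera adjusted p = 5.88e-12, and adjusted p = 0.0629 with an estimated correlation). Lower too were 65 of 71 oxidative phosphorylation genes (camera adjusted p = 1.47e-12, and 0.283 with an estimated correlation). So were 19 of 20 endoplasmic reticulum stress genes (2.08e-08 and 0.0629) and 17 of 20 citric acid cycle genes (7.19e-08 and 0.101). Further lists were called with the preset correlation. The skeletal muscle list was called lower there, with 6 of 19 genes lower and 1 higher (camera adjusted p = 2.94e-05, and adjusted p = 0.0127 with an estimated correlation). It was the only list whose call held with an estimated correlation. Still, only 9 of its genes passed the filter within batch 13 against 19 in batch 12. The effect of the others in batch 13 rests on few counts, so no conclusion is drawn from this call. The brown thermogenic list was not called (camera adjusted p = 0.177), and 16 of its genes passed the filter within batch 12 against 22 in batch 13.

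To ask how far each group carried the KO-EBF2 profile, genes changed at least 2-fold between KO-EBF2 and KO-EV in one batch were scored in the libraries of the other. Of the 1179 genes higher in batch 12, 1129 were tested in batch 13, and their median log2 fold change over KO-EV there was 0.90 in KO-EBF2, 1.73 in KO-FUS, 1.19 in KO-IDR, 0.45 in KO-P>A and -0.04 in KO-MED1. The numbers of these genes called higher and lower were 805 and 67 in KO-EBF2, 1000 and 34 in KO-FUS, 894 and 51 in KO-IDR, 591 and 12 in KO-P>A, and 364 and 413 in KO-MED1. Camera did not call this set in KO-MED1 (adjusted p = 0.258). With no minimum fold change the median there was 0.16, and camera called the set higher (adjusted p = 0.0227). Of the 1041 genes lower in batch 12, 983 were tested, with medians of -0.74, -1.35, -1.03, -0.11 and -0.30 in the same order. The KO-P>A (camera adjusted p = 0.00167) and KO-MED1 (0.0118) calls for these lower genes were lost with an estimated correlation (adjusted p = 0.0682 and adjusted p = 0.129).

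Set directly against KO-EBF2 in batch 13, the higher genes had a median difference of 0.78 in KO-FUS (camera adjusted p = 3e-13, and adjusted p = 0.00667 with an estimated correlation), -0.44 in KO-P>A (2.63e-10 and 0.0134) and -0.91 in KO-MED1 (1.71e-15 and 0.00509). The lower genes differed by -0.57 in KO-FUS (camera adjusted p = 9.47e-06, and adjusted p = 0.0174 with an estimated correlation) and 0.60 in KO-P>A (8.24e-13 and 0.00321). In KO-MED1 they differed by 0.52 (camera adjusted p = 0.00109), a call lost with an estimated correlation (adjusted p = 0.0617) and with no minimum fold change (adjusted p = 0.235). In KO-IDR the differences were 0.25 and -0.26 (camera adjusted p = 0.00369 and 0.00531), and these calls were lost with an estimated correlation (adjusted p = 0.160 and adjusted p = 0.102). In the other direction, genes of batch 13 were scored in batch 12, where 1056 of 1229 higher and 989 of 1033 lower genes were tested. KO-EBF2 had medians of 0.89 and -0.80 and KO-CTD of 0.24 and -0.16. The differences of -0.72 and 0.62 between these groups passed the test (camera adjusted p at most 6.14e-15, and adjusted p = 0.00851 with an estimated correlation for both).

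**Figure D3:**
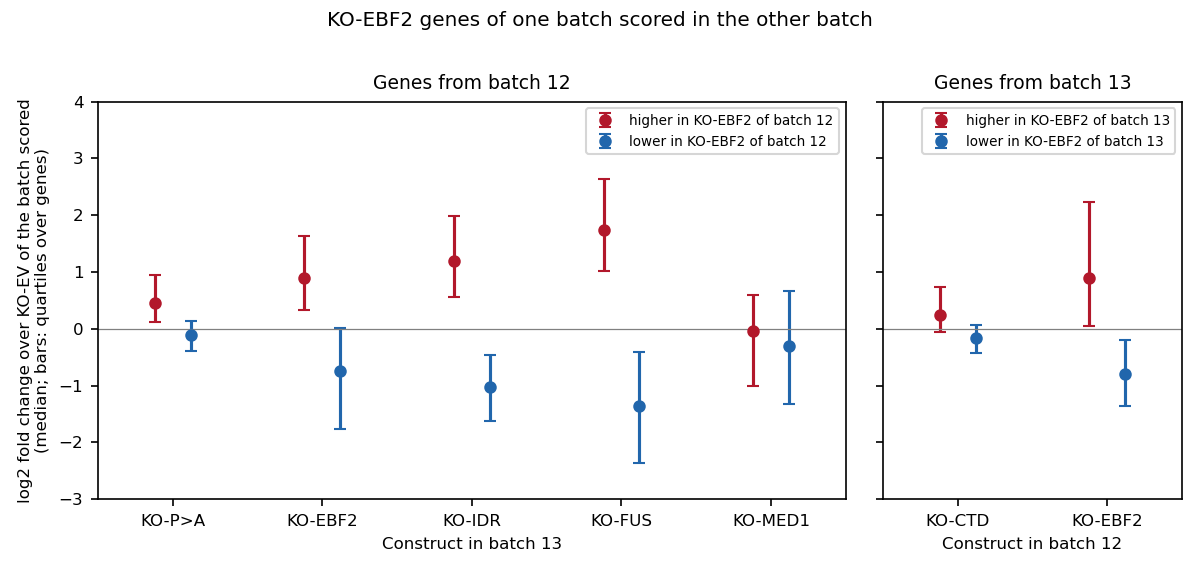
Median log2 fold change over KO-EV (vertical) of genes changed at least 2-fold between KO-EBF2 and KO-EV in the other batch, by group (horizontal). Red is genes higher and blue genes lower in KO-EBF2, and bars span the quartiles over genes; for batch 12 genes the red medians run from -0.04 in KO-MED1 to 1.73 in KO-FUS.

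KO-FUS had the highest Ucp1 and Cidea levels of the 6 groups of batch 13. Ucp1 reached 25.4 ± 2.31 CPM against 3 counts in KO-EV, a ratio of 512 (175 to 2480; edgeR adjusted p = 1.63e-13). It exceeded KO-EBF2 by 4.05 ± 0.24 on the log2 scale (edgeR adjusted p = 1.63e-11). Dio2, the deiodinase that makes active thyroid hormone in brown fat, was at 35.2 ± 2.85 CPM against 0 counts in KO-EV, at least 234-fold higher, and 8.82 ± 0.30 above KO-EBF2 (edgeR adjusted p = 9.53e-12). Cidea had a ratio of 824 over KO-EV (228 to 6810), and Adamtsl2 rose by 9.16 ± 0.24. Adipoq stood at 804 ± 75.4 CPM, 3.87 ± 0.08 over KO-EV and 1.89 ± 0.07 over KO-EBF2. Pparg stood at 240 ± 11.0 CPM, 2.38 ± 0.08 and 0.78 ± 0.07 (edgeR adjusted p at most 5.49e-09). Dnah1 (-8.39 ± 0.35), Col11a1 (-6.83 ± 0.35) and Edil3 (-5.91 ± 0.24) fell from KO-EV, and Zxda, whose reads can be shared with a close copy, was at least 56.2-fold lower. Over KO-EBF2, Sgce (8.91 ± 0.26), Unc93b1 (8.27 ± 0.19) and Peg10 (at least 71.9-fold) were higher. Sorcs1 (-3.83 ± 0.13), the copper transporter gene Atp7a (-4.06 ± 0.20), and Zbed6 and Zxda, with uncertain counts, were lower. The test called 10926 genes against KO-EV, 5512 higher and 5414 lower. Against KO-EBF2 it called 10377, 5214 higher and 5163 lower.

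All 71 oxidative phosphorylation genes rose in KO-FUS over KO-EV (71 adjusted over the list alone), with a median of 1.67 (camera adjusted p = 1.37e-19, and adjusted p = 0.268 with an estimated correlation). Cycs had a log2 fold change of 2.77 ± 0.07. All 71 also rose over KO-EBF2, with a median of 1.30 (71 adjusted over the list alone; camera adjusted p = 7.33e-21, and adjusted p = 0.338 with an estimated correlation). All 13 mitochondrially encoded genes rose over KO-EV (13 adjusted over the list alone; camera adjusted p = 8.48e-05, and adjusted p = 0.347 with an estimated correlation), and they made up 3.95% ± 0.04 of counts, the highest share of any group of batch 13. Brown thermogenic genes rose in 16 of 22 cases over KO-EV, with a median of 2.31 (16 adjusted over the list alone; camera adjusted p = 0.000656, and adjusted p = 0.0606 with an estimated correlation). Over KO-EBF2 15 of 22 were higher and 5 lower (20 adjusted over the list alone; camera adjusted p = 0.00819, and adjusted p = 0.338 with an estimated correlation). Cidea had a log2 fold change of 3.61 ± 0.17 and Cox7a1 of 2.17 ± 0.12. All 30 general adipocyte genes rose over KO-EV (30 adjusted over the list alone; camera adjusted p = 1.16e-11, and adjusted p = 0.0606 with an estimated correlation). Of these genes 23 were higher and 2 lower than in KO-EBF2 (25 adjusted over the list alone; camera adjusted p = 0.000434, and adjusted p = 0.354 with an estimated correlation). Interferon response genes were higher than in KO-EV in 24 of 25 cases and lower in 1 (25 adjusted over the list alone; camera adjusted p = 5.94e-08, and adjusted p = 0.347 with an estimated correlation). Extracellular matrix genes were lower than in KO-EV in 26 of 30 cases and higher in 4 (30 adjusted over the list alone; camera adjusted p = 1.46e-06, and adjusted p = 0.149 with an estimated correlation). Thbs2 had a log2 fold change of -3.52 ± 0.06.

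In KO-IDR, Ucp1, Adipoq and Pparg also stood above KO-EBF2. Ucp1 was at 12.3 ± 1.79 CPM, a ratio of 244 over KO-EV (83.1 to 1180; edgeR adjusted p = 1.37e-11) and 2.90 ± 0.25 above KO-EBF2 (edgeR adjusted p = 6.2e-09). Adipoq stood at 342 ± 19.7 CPM, 2.53 ± 0.07 over KO-EV and 0.55 ± 0.07 over KO-EBF2. Pparg stood at 235 ± 1.30 CPM, 2.26 ± 0.08 and 0.65 ± 0.07 (edgeR adjusted p at most 4.77e-07). Mb rose by 7.10 ± 0.15 over KO-EV to 239 CPM, Cidea had a ratio of 231 (63.7 to 1910), and the cytoskeletal gene Dpysl3 (-3.89 ± 0.09), Grem1 (-3.76 ± 0.11), Edil3 (-3.61 ± 0.19) and Spon2 (-3.38 ± 0.16) fell. Pagr1a, with uncertain counts, was called higher (7.01 ± 1.36). Over KO-EBF2, Dnah1 had a ratio of 854 (236 to 7050), Zdhhc15 of 913 (164 to 36100) and Kcne4 rose by 6.70 ± 0.25. Peg10 was at least 13.2-fold higher, and Sorcs1 (-8.54 ± 0.22), Syt13 (-6.70 ± 0.30) and the matrix gene Fmod (-6.38 ± 0.29) fell. Rps12l1, a close copy of another gene and so uncertain, was at least 691-fold lower. The test called 8921 genes against KO-EV, 4558 higher and 4363 lower. Against KO-EBF2 it called 8690, 4424 higher and 4266 lower.

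Of the 13 lists called in KO-IDR against KO-EV, 5 held with an estimated correlation. Over KO-EV, general adipocyte genes were higher in 28 of 30 cases and lower in 1 (29 adjusted over the list alone; camera adjusted p = 9.92e-14, and adjusted p = 0.0270 with an estimated correlation). Brown thermogenic genes rose in 17 of 22, with a median of 1.66 (17 adjusted over the list alone; camera adjusted p = 4.87e-05, and adjusted p = 0.0270 with an estimated correlation). Brown thermogenic genes were also higher than in KO-EBF2 in 16 of 22 cases and lower in 4 (20 adjusted over the list alone; camera adjusted p = 0.00582, and adjusted p = 0.231 with an estimated correlation). The citric acid cycle (20 of 20, 20 adjusted over the list alone; camera adjusted p = 6.55e-13) and fatty acid oxidation (21 of 22, 21 adjusted over the list alone; camera adjusted p = 3.31e-12) lists rose, both with adjusted p = 0.0270 with an estimated correlation. Cholesterol synthesis genes fell in 17 of 21 cases (18 adjusted over the list alone; camera adjusted p = 2.96e-07, and adjusted p = 0.0316 with an estimated correlation). Cyp51 had a log2 fold change of -1.35 ± 0.07. Oxidative phosphorylation genes rose in 70 of 71 cases (70 adjusted over the list alone; camera adjusted p = 4.92e-21, and adjusted p = 0.238 with an estimated correlation), and mitochondrially encoded counts made up 2.5% ± 0.56. Inflammatory genes were lower in 8 of 14 cases and higher in 1 (9 adjusted over the list alone; camera adjusted p = 0.0181, and adjusted p = 0.301 with an estimated correlation). Vcam1 stood at -1.98 ± 0.07. Interferon response genes were higher than in KO-EV in 16 of 25 cases and lower in 1 (17 adjusted over the list alone; camera adjusted p = 0.00794, and adjusted p = 0.615 with an estimated correlation). They were lower than in KO-EBF2 in 22 of 25 (22 adjusted over the list alone; camera adjusted p = 7.49e-09, and adjusted p = 0.374 with an estimated correlation). Gbp2 had a log2 fold change of -1.76 ± 0.08.

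KO-MED1 was the group in which fat cell transcripts stood below KO-EV of batch 13, which itself held them (Adipoq at 59.1 ± 3.40 CPM). Adipoq was at 0.377 ± 0.0869 CPM, a log2 fold change of -7.25 ± 0.15 against KO-EV and -9.23 ± 0.14 against KO-EBF2 (edgeR adjusted p at most 1.8e-19). Ucp1 had 0 counts and was at least 13.7-fold lower than in KO-EBF2. Pparg was at 41.3 ± 1.85 CPM, -1.84 ± 0.08 against KO-EBF2 (edgeR adjusted p = 1.66e-14) and -0.23 ± 0.08 against KO-EV (edgeR adjusted p = 0.0153), a call lost without KO-EV replicate 6 (-0.09; edgeR adjusted p = 0.223). Also lower than in KO-EV were Rspo2, a secreted activator of Wnt signalling (-8.09 ± 0.19), the nicotinic acid receptor gene Hcar2 (at least 10.9-fold), Retn (ratio 0.00287, 0.000590 to 0.00840) and the receptor gene Acvr1c (ratio 0.00302, 7.61e-05 to 0.0169). Syt13 (7.71 ± 0.29), Tmem178 (6.90 ± 0.20), the annexin gene Anxa8 (6.09 ± 0.26) and Ppp2r2b (ratio 507, 140 to 4190) were higher. Against KO-EBF2, Car3 (-12.07 ± 0.23), Cidec (-9.99 ± 0.18), Hcar2 (at least 107-fold) and Acvr1c (ratio 0.000614, 1.55e-05 to 0.00343) were lower. Ces2g (7.44 ± 0.26), Ripk3, a kinase of necroptosis (6.5 ± 0.22), Zdhhc15 (ratio 211, 37.6 to 8380) and Peg10 (at least 4.10-fold) were higher. The test called 10059 genes against KO-EV, 5210 higher and 4849 lower. Against KO-EBF2 it called 10053, 5080 higher and 4973 lower.

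General adipocyte genes were lower in KO-MED1 than in KO-EV in 28 of 30 cases and higher in 2 (30 adjusted over the list alone), with a median of -3.39 (camera adjusted p = 2.35e-10, and adjusted p = 0.110 with an estimated correlation). Klf15, a transcription factor of fat cells, stood at -4.12 ± 0.12. All 30 were lower than in KO-EBF2, with a median of -4.66, or -4.07 with bounds, and this call held with an estimated correlation (30 adjusted over the list alone; camera adjusted p = 4.06e-18, and adjusted p = 0.0353). Oxidative phosphorylation genes were higher than in KO-EV in 60 of 71 cases (61 adjusted over the list alone; camera adjusted p = 3.74e-08, and adjusted p = 0.396 with an estimated correlation). All 13 mitochondrially encoded genes were higher too (13 adjusted over the list alone; camera adjusted p = 9.58e-05, and adjusted p = 0.293 with an estimated correlation), and made up 2.81% ± 0.10 of counts. Brown thermogenic genes were lower in 11 of 22 cases and higher in 2 and were not called (13 adjusted over the list alone; camera adjusted p = 0.0523). Extracellular matrix genes were lower in 26 of 30 cases and higher in 1 (27 adjusted over the list alone; camera adjusted p = 2.01e-08, and adjusted p = 0.110 with an estimated correlation). Postn had a log2 fold change of -5.59 ± 0.07. Among smooth muscle genes, Acta2 stood at 47.6 ± 3.51 CPM against 560 ± 38 in KO-EV. The camera call of the smooth muscle list was lost with an estimated correlation. All 5 bone and cartilage markers fell (5 adjusted over the list alone; camera adjusted p = 0.00359, and adjusted p = 0.157 with an estimated correlation). Interferon response genes were higher in 24 of 25 cases and lower in 1 (25 adjusted over the list alone; camera adjusted p = 3.74e-08, and adjusted p = 0.293 with an estimated correlation). Cxcl10 had a log2 fold change of 3.67 ± 0.14. Proliferation genes were higher in 22 of 32 cases and lower in 3 (25 adjusted over the list alone; camera adjusted p = 0.000396, and adjusted p = 0.209 with an estimated correlation). The cell cycle kinase gene Cdk1 had a log2 fold change of 1.08 ± 0.04.

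KO-P>A had the highest Ebf2 level of batch 13, with Adipoq and Pparg above KO-EV and below KO-EBF2. Adipoq stood at 155 ± 10.5 CPM, 1.38 ± 0.07 over KO-EV and -0.60 ± 0.07 against KO-EBF2. Pparg stood at 98.8 ± 3.81 CPM, 1.00 ± 0.08 and -0.61 ± 0.08 (edgeR adjusted p at most 6.81e-07). Ucp1 did not pass the test against KO-EV, at 11 counts against 3, a ratio of 3.40 (0.898 to 19.0; edgeR adjusted p = 0.286). It was lower than in KO-EBF2 by a log2 fold change of -3.24 ± 0.50 (edgeR adjusted p = 1.77e-05). Tmem178 (3.26 ± 0.30), Cyp2f2 (2.77 ± 0.20) and Pagr1a, with uncertain counts (5.64 ± 1.56; edgeR adjusted p = 0.0109), were higher than in KO-EV. Cth (-1.34 ± 0.12), the preadipocyte factor gene Dlk1 (-1.14 ± 0.08), Stc2 (-1.12 ± 0.18) and Neto2 (-1.12 ± 0.20) were lower. Against KO-EBF2, Peg10 (at least 130-fold), Sgce (9.20 ± 0.26), Zdhhc15 (ratio 730, 131 to 28900) and Dnah1 (ratio 486, 134 to 4020) were higher. Car3 (-5.22 ± 0.13), Sorcs1 (-4.85 ± 0.15), Ppp2r2b (at least 59.5-fold) and Cidea (3 counts, ratio 0.0184, 0.00374 to 0.0546) were lower. The test called 3486 genes against KO-EV, 1784 higher and 1702 lower. Against KO-EBF2 it called 7781, 3660 higher and 4121 lower.

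General adipocyte genes were higher in KO-P>A than in KO-EV in 28 of 30 cases and lower in 1 (29 adjusted over the list alone), with a median of 1.22, a call that held with an estimated correlation (camera adjusted p = 7.51e-23, and adjusted p = 0.0144). Lipid synthesis genes rose in 15 of 18 cases (16 adjusted over the list alone; camera adjusted p = 7.68e-12, and adjusted p = 0.0882 with an estimated correlation). Scd1 had a log2 fold change of 1.43 ± 0.13. Interferon response genes rose in 22 of 25 (22 adjusted over the list alone; camera adjusted p = 2.13e-15, and adjusted p = 0.152 with an estimated correlation). The interferon rises of batch 13 all share the same 3 KO-EV libraries. Isg15 stood at 56.3 CPM in these and, set beside them without a test, at 168 in KO-EV of batch 12. KO-P>A (79.2) and KO-IDR (84.9) lay below that batch 12 level, and KO-EBF2 (197), KO-FUS (313) and KO-MED1 (249) above it. Brown thermogenic genes rose in 5 of 22 cases (5 adjusted over the list alone; camera adjusted p = 0.00661, and adjusted p = 0.118 with an estimated correlation). Kcnk3 had a log2 fold change of 2.01 ± 0.10. Mitochondrially encoded genes, at 1.00% ± 0.04 of counts, fell in 5 of 13 cases (6 adjusted over the list alone; camera adjusted p = 0.00661, and adjusted p = 0.457 with an estimated correlation). The oxidative phosphorylation list was not called, with 5 of 71 genes higher and 1 lower (2 adjusted over the list alone; camera adjusted p = 0.158). Against KO-EBF2, oxidative phosphorylation genes were lower in 45 of 71 cases and higher in 2 (47 adjusted over the list alone; camera adjusted p = 9.67e-06, and adjusted p = 0.550 with an estimated correlation). Fatty acid oxidation genes were lower in 20 of 22 (21 adjusted over the list alone; camera adjusted p = 7.62e-10, and adjusted p = 0.0667 with an estimated correlation). Extracellular matrix genes were higher than in KO-EBF2 in 23 of 30 cases and lower in 1 (24 adjusted over the list alone; camera adjusted p = 5.57e-10, and adjusted p = 0.0667 with an estimated correlation). Mmp2 had a log2 fold change of 2.42 ± 0.05. Smooth muscle genes were higher in 9 of 11 and lower in 1 (11 adjusted over the list alone; camera adjusted p = 1.75e-05, and adjusted p = 0.0667 with an estimated correlation). Myl9 had a log2 fold change of 1.86 ± 0.08.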

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

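The tests of the mixing, of a library that carries the signal, of culture conditions, of abundant genes, of a batch 12-like state and of the adipocyte share were chosen after their results or the patterns had been seen. The effect of KO-EBF2 over KO-EV differed between the batches in 7756 of 14093 genes by the test of the difference itself, and 6 genes named by rule went in opposite directions in the batches. Given as batch 13 minus batch 12 on the log2 scale with edgeR adjusted p, Fus differed by 0.63 ± 0.08 (2.96e-07; -0.23 in batch 12 and 0.39 in batch 13). Dcn differed by 5.80 ± 0.18 (edgeR adjusted p = 2.79e-19; -3.55 and 2.25) and Saa3 by 4.40 ± 0.35 (5.33e-11; -3.43 and 0.96). Sgce differed by -10.62 ± 0.56 (edgeR adjusted p = 1.38e-14; 3.39 and -7.26) and Unc93b1 by -7.26 ± 0.30 (8.94e-17; 0.79 and -6.47). For Peg10 the fitted difference was -13.5 ± 1.1 (edgeR adjusted p = 1.83e-10), a value that depends on the prior count because KO-EBF2 of batch 13 had 0 counts.

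The first pattern weighed was that KO-EV of batch 13 held more adipocyte transcript than KO-EV of batch 12. The median log2 difference over the general adipocyte genes was 2.224, and the lowest batch 13 KO-EV library still stood 2.058 above the batch 12 mean, so a single KO-EV library does not carry it. Against cells or RNA of the KO-EBF2 culture of batch 13 mixed into KO-EV, a first test of the share needed for Ebf2 over that needed for the adipocyte genes gave a ratio of 0.453, or 0.682 with Ebf2 raised by 2 SE, and left it undecided. A second test, with thresholds set after those values were seen, found 11 of 9689 genes of at least 10 CPM in KO-EBF2 at under 0.05 of that level in KO-EV, such as Tmem178 at 0.453% and Car3 at 0.518%, where a mix would have to bring the median adipocyte share of 17.7%, which argues against a mix. Other cell lots, passage or culture conditions in batch 13 cannot be told apart from the batch, because each batch has its own KO-EV libraries only, and a biological difference between the batches was not tested.

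The second pattern was that KO-FUS and KO-MED1 stood apart from the other groups of batch 13. An axis was built on 283 genes that differed at least 2-fold between the KO-EV groups of the batches (edgeR adjusted p under 0.05). None of them was called for KO-EBF2 against KO-EV in either batch. By construction the axis is near 0 for KO-EBF2 and KO-EV of batch 12 and near 1 for those of batch 13. KO-CTD of batch 12, not used to set the scale, stood at 0.021. In batch 13 KO-MED1 stood at 0.247, KO-FUS at 0.137, KO-IDR at 0.595 and KO-P>A at 1.07. The top 10 genes took 7.16% of counts in KO-FUS and 5.66% in KO-MED1, so a few genes did not take most of the counts. Both lay at a distance of 0 percentage points from the 5.37% to 7.25% of the other groups of both batches. The upper end of that range was KO-EBF2 of batch 12. Within batch 13 the highest other group was KO-P>A at 6.46%, below KO-FUS. That KO-FUS and KO-MED1 were grown or prepared apart from the rest of batch 13 stays open, since the labels name no such split and the groups' own effects cannot be told apart from it. KO-IDR lay between, at 0.474 to 0.652 by library, where a split of just those groups would leave it near the controls of batch 13. The comparisons of KO-FUS, KO-MED1 and KO-IDR with KO-EV and KO-EBF2 of batch 13 may include such a difference. Set beside KO-EV of batch 12 without a test, KO-MED1 had Adipoq at 0.377 CPM against 0.721, Plin1 at 1.41 against 1.38 and Fabp4 at 99.6 against 83.9. Cebpa was lower in KO-MED1, at 7 against 21.7, and Pparg higher, at 41.3 against 27.3. KO-EV of batch 13 stood above both groups for these genes, with Adipoq at 59.1.

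The third pattern was that KO-FUS exceeded KO-EBF2 in brown fat genes. A batch 12-like state was tested by setting KO-FUS against KO-EBF2 of batch 12. KO-FUS stood higher by a median of 1.36 over the brown thermogenic genes tested in batch 13 (19 of 22 higher, quartiles 0.19 and 2.99). Genes of that set that failed the filter in batch 12 were low in its KO-EBF2, so the set leans towards KO-FUS. Over those tested in both batches the median was 0.427 (13 of 16 higher, quartiles 0.11 and 1.43), within the bound set for such a state. The rule asked for both sets to lie within that bound, so the test left this state undecided. For a higher share of adipocytes raising all adipocyte genes alike, the first test compared the medians of the brown and general lists (difference 0.24, two-sided permutation p = 0.411 over 52 genes) and came out in its favour. After that result the test was changed to the number of members called lower in KO-FUS, 7 of 52, with Car3 at -3.10. Over all genes, 5163 of 13786 were called lower. A higher share alone would lower none of these members, but the changed test cannot exclude a higher share that acts beside another difference. The construct itself, which the design names, separate preparation as above and a batch 12-like state stay open, as does a higher share beside any of them.

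Other splits of the same libraries were counted for each comparison. Each of the 12 comparisons had 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes. The real counts and the highest of the other splits were 8555 and 0 for KO-EBF2 (the 9 others all gave 0 genes, both the 3 that part all 3 pairs of libraries and the 6 that part 1), 2093 and 0 for KO-CTD, both against KO-EV, and 7412 and 0 for KO-CTD against KO-EBF2 in batch 12. Against KO-EV in batch 13 they were 8754 and 1 for KO-EBF2, 10926 and 0 for KO-FUS, 8921 and 27 for KO-IDR, 10059 and 0 for KO-MED1, and 3486 and 1 for KO-P>A. Against KO-EBF2 they were 10377 and 0 for KO-FUS, 8690 and 0 for KO-IDR, 10053 and 0 for KO-MED1, and 7781 and 0 for KO-P>A. For the difference between the batches, 1 of 100 drawn splits, the real one, gave as many genes. Splits that mix KO-EBF2 with KO-EV remove the effect of the group itself, so none stands for the same effect in both batches. The count therefore cannot tell whether chance gave the difference. The highest other split gave 6025 and kept the groups of 1 batch intact, as did all 16 splits with any call, and the 83 splits that kept neither gave 0 genes.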

How the results depend on the processing

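The alternatives chosen after the data were seen were size factors for the lists, batch 13 results without KO-IDR replicate 4 and an estimated correlation for the transfer; the others were planned. Of 155 counts of changed genes under an alternative, 152 lay within 1.5 times the reported count. The exceptions were 1184, 1277 and 1322 genes for KO-CTD against KO-EV (reported 2093) without KO-CTD replicate 3, KO-EV replicate 2 and KO-CTD replicate 1, and the highest value with a library left out was 2516. Fewer samples are tested there, and the cause was not tested further. With an estimated correlation, camera called 0 lists in 9 comparisons: KO-EBF2 (reported 11) and KO-CTD (12) against KO-EV and KO-CTD against KO-EBF2 (12) in batch 12, and KO-EBF2 (13), KO-FUS (10) and KO-MED1 (13) against KO-EV and KO-FUS (9), KO-IDR (11) and KO-P>A (11) against KO-EBF2 in batch 13. It called 5 of the 13 for KO-IDR and 1 of the 11 for KO-P>A against KO-EV, and 1 of the 11 for KO-MED1 against KO-EBF2. The estimated correlation of list members was over the preset 0.01 in 127 of the 130 calls lost this way, with a median of 0.218. Fry, which does not compare a list with other genes, called fewer lists for KO-CTD against KO-EV (9, reported 12) and more elsewhere: 19 for KO-EBF2 against KO-EV in batch 12, 20 for KO-CTD against KO-EBF2, 19, 20, 21, 20 and 16 for KO-EBF2, KO-FUS, KO-IDR, KO-MED1 and KO-P>A against KO-EV in batch 13, and 18, 18, 17 and 17 for KO-FUS, KO-IDR, KO-MED1 and KO-P>A against KO-EBF2. Among single lists, 640 results kept their call and 140 lost it, 130 of them with an estimated correlation.

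In the transfer of profiles between the batches, in both directions, 294 results kept their call. With an estimated correlation the calls of KO-IDR against KO-EBF2 (0.253 for higher genes, adjusted p = 0.160; -0.261 for lower, 0.102), of the lower genes of KO-MED1 against KO-EV (-0.304; 0.129) and against KO-EBF2 (0.523; 0.0617), and of KO-P>A against KO-EV (-0.111; 0.0682) were lost. With no minimum fold change, the higher genes of KO-MED1 against KO-EV turned from -0.037 to 0.164 (adjusted p = 0.0227), and the lower genes against KO-EBF2 fell to 0.045 (adjusted p = 0.235); the cause was not tested. For KO-EBF2 against KO-EV in batch 12 the numbers may pair the libraries. There the replicate block gave 8650 genes (reported 8555) and 11 lists and changed no call of a single gene or list. Elsewhere the libraries share only a number: same-numbered libraries correlated over 0.1 in 0 of the 6 other pairs in batch 12 and 5 of 45 in batch 13, and 5 of 9 and 4 of 18 libraries lay closest to their own number. With the replicate number as a block, no count of genes, lists or transfer left its bounds, the lists called for KO-IDR and KO-MED1 against KO-EV were 12 and 14, 1 single list lost its call, and 5 genes gained one, among them Stat1, Ifit2 and Oasl1 in KO-CTD against KO-EV. Of the values for 1158 pairs of gene and comparison, 13250 kept their call, 93 lost it (88 with a library left out), 36 gained one and 15 changed sign. All 15 were Med1 folds near 0 that did not pass the test. With a library left out they ran from -0.12 to 0.03 for KO-CTD, -0.11 to 0.01 for KO-EBF2 of batch 13, -0.21 to 0.04 for KO-IDR and -0.10 to 0.01 for KO-P>A against KO-EV, and from -0.16 to 0.12 for KO-IDR and -0.04 to 0.07 for KO-P>A against KO-EBF2. The last was 0.01 with DESeq2 and with its size factors, 0.03 with no filter and 0.02 in a fit of only the 2 groups (reported 0.00). The correlation of the batches across genes was lowest with no filter on low counts (Pearson r = 0.239, Spearman rho = 0.251). TMM and size factors placed the median of all genes within 0.1 of 0. Both methods centre the bulk of genes near 0, so this cannot exclude a shift of all genes. Depth limits the calls for Ucp1 and Cidea in KO-EV, at 0 to 3 counts over 3 libraries.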

Other observations

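The observations below were chosen after the data were seen. Genes that changed at least 16-fold between KO-EBF2 and KO-EV were split by how they behaved in the other batch. In batch 12, 185 genes were higher by that much, and of the 165 tested in batch 13, 132 were called higher there, 3 lower and 30 not called. In batch 13, 110 genes were higher, and of the 50 tested in batch 12, 35 were called higher, 3 lower and 12 not called. Falls of that size were more numerous in batch 13, with 136 genes against 16 in batch 12. Of the 12 batch 12 falls tested in batch 13, 5 were called lower, 2 higher and 5 not called. Of the 124 batch 13 falls tested in batch 12, 77 were called lower, 9 higher and 38 not called.

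Some genes ranged from 0 or a few counts to clear expression between the groups of batch 13, with other groups in between. Peg10 and Sgce, neighbouring imprinted genes, stood at 3.97 and 12.9 CPM in KO-EV, 0 and 0.0734 in KO-EBF2, 10.7 and 37.4 in KO-FUS, 1.96 and 3.51 in KO-IDR, 0.610 and 0.727 in KO-MED1, and 19.3 and 49.3 in KO-P>A. Dnah1 stood at 23.0 CPM in KO-EV, 28.4 in KO-IDR, 15.9 in KO-P>A, 0.132 in KO-MED1, 0.0608 in KO-FUS and 0.0360 in KO-EBF2. Zdhhc15 stood at 13.1 CPM in KO-EV, 15.0 in KO-IDR, 12.0 in KO-P>A, 3.46 in KO-MED1, 0.915 in KO-FUS and 0.0140 in KO-EBF2. The SD between the 3 libraries was 2.05 for Peg10 in KO-EV, 6.34 for Dnah1 in KO-IDR, and 2.27 in KO-EV and 0.805 in KO-FUS for Sgce. No test of an explanation was run for them.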
